A study of Homo sapiens with 6 samples.

How the data were processed

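Total RNA from LP-1 cells was extracted with a column kit, amplified, and turned into biotin-labelled single-stranded cDNA, which was hybridized to 6 arrays of gene-level transcript clusters. LP-1 is an established human multiple myeloma line. The medium was RPMI-1640 with 15% serum, 23.8 mM bicarbonate and 2 mM GlutaMAX at 37 °C in 5% CO2. The arrays fall into 3 groups of 2 described as biological replicates: control culture (Ctrl), short-term acid culture (SA) and long-term acid culture (LA).

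The deposited values are taken to be on a log2 scale, made by the authors with RMA, a method that corrects background, quantile-normalizes the arrays against each other and summarizes the probes of each cluster. The processing notes name RMA and the Transcriptome Analysis Console without versions or parameters. The log base and the variant of RMA are not given in the sources used here, so the size of every fold rests on the base being 2. Values reached about 20, beyond the range of a 16-bit scanner on a log2 scale, and the reason is not given in the sources used here. No detection calls were given, and many of the largest differences run against a group near the array median of 3.77.

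The table held 135574 probe sets, of which 36176 carried 1 gene symbol, 1119 several and 98279 none in the annotation used here. Of 25555 single-symbol probe sets with a gene ID, 25516 matched the human gene table of assembly GRCh38.p14. The array's own genome build is not given in the sources used here, so that table served only for current symbols, gene type, chromosome and the order of neighbouring genes. Where a symbol had several probe sets, the brightest over the 6 arrays was used. Genes with a mean at or above the median of all probe sets, 3.77, were kept, which left 21070 genes, 12038 of them protein coding.

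Groups were compared in R 4.3.3 with limma 3.58.1, using group means over all 6 arrays, empirical Bayes moderation without a trend, and p-values of the two-sided moderated test adjusted by Benjamini-Hochberg over the genes kept. A gene was called at an adjusted p under 0.05. Errors of differences are standard errors from limma without a replicate block, and errors of group levels are SDs of 2 arrays. The number of arrays limits the precision: an exact permutation test of 2 against 2 arrays has 6 arrangements and cannot go below p = 0.333, so single genes were tested only with limma, which pools the spread over genes.

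The table as deposited held almost no difference between replicate 1 and replicate 2 arrays. Replicate number took 1.18% of the within-group sum of squares, where 33.3% would be expected and 100 simulations without any removal gave 32.6% to 33.9%. The simulated genes were drawn independently of each other, so that range leaves out errors shared by genes. The labels state no removal of a replicate term. A fit that takes no account of the missing difference counts 3 residual degrees of freedom where 2 are left, so its p-values are too small. The standard errors given come from that fit, and the SDs of 2 arrays lack the same term. Both therefore tend to be too small as well. For that reason counts with replicate number as a block are given beside the main ones for each comparison and each list called.

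Both fits were tested on simulated data with known changes, with spreads drawn from the prior of the blocked fit and the replicate term removed. Without the block, 10.9% of unchanged genes had an unadjusted p under 0.05 in each comparison, and 14.4%, 7.41% and 11.5% of calls were false in SA minus Ctrl, LA minus Ctrl and LA minus SA. With the block, the unchanged share was 5.33%, 4.93% and 4.94%, and the false share of calls 8.65%, 4% and 6.12%. The block recovered 82% to 88% of changes of 2 on the log2 scale and 0% to 4% of changes of 1. Drawing each gene at its own estimated spread instead let the block call 10, 19 and 32 of 200 changed genes and the fit without it 88, 102 and 100; the draw from the prior was chosen after such a run had been seen. A drop of 1 in the mitosis list was recovered by the set test in each comparison, with 0, 0 and 1 of the other lists called. The simulated genes were drawn independently of each other, so this does not test the set test on correlated genes.

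The 42 gene lists, the rule for named genes, the tests of the comparisons and lists, and all but 1 of the alternatives were fixed before the data were examined; tests of single patterns that were chosen later are named where their values are given. Lists with at least 5 genes kept, 41 in all, were tested against the other genes with camera from limma at a preset correlation of 0.01, adjusted over the lists; camera with an estimated correlation and fry, which tests a list on its own, served as alternatives. With an estimated correlation, 0 of the 41 lists were called in any comparison. The list of small nucleolar RNA host genes kept 3 genes and was not tested; 1 of them, SNHG19, was called in SA minus Ctrl, at -1.64. Named genes are, per comparison, the 10 largest rises and 10 largest falls among called genes whose arrays did not overlap between the groups, up to 2 called members in each direction per list, and 26 genes of acid handling, metabolism and plasma cells given whether called or not. Symbols of unnamed loci, small RNAs, antisense transcripts, immunoglobulin segments and Y-linked genes were left out of the largest changes. Some results that fall under these rules are not reported here.

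The alternatives were other filters on dim genes, other scalings, the mean over the probe sets of a gene, every probe set, trended and robust variance models, only the groups compared, the block, other thresholds, other set tests, and each array left out in turn. Removing each chromosome's median deviation from each array was added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Probe sets with several symbols were left out because their signal cannot be given to 1 gene. SLC16A1, SLC16A3 and CA9 had no single-symbol probe set and were not analysed here. ASIC1 and FGFR3 had means of 3.48 and 3.32, below the filter, and were not tested.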

Results

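Gene expression was measured on 6 arrays in LP-1 cells, a human multiple myeloma line that represents malignant plasma cells. Ctrl cells were kept at an extracellular pH (pHe) of 7.4 with a time label of 9 months. SA cells were kept at pHe 6.8 with a time label of 2 weeks, and LA cells at pHe 6.8 with a time label of 9 months, 2 arrays per group. The time of the SA cells is given as 2 to 3 weeks in the sample descriptions and as 2 to 4 weeks in the series design. The time of the LA cells is given as 8 to 10 weeks in the sample descriptions and as 8 to 10 months in the series design. The SA cells, by their labels, also differed from both other groups in time in culture. The first principal component held 54.6% of the variance and set the SA arrays, at 56 and 59.71, apart from the Ctrl arrays, at -15.56 and -21.68, and the LA arrays, at -40.58 and -37.88. The second held 23.9% and separated Ctrl from LA.

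The comparison of SA with Ctrl asks what weeks at pHe 6.8 change in these cells. Lists of mitosis, DNA replication, sterol and fatty acid synthesis and glycolysis genes moved down in SA cells, and lists of immediate early, integrated stress response, unfolded protein response and plasma cell genes moved up, in a set test at a preset correlation. With an estimated correlation, 0 of the 41 lists were called by limma camera and 3 had an unadjusted p under 0.05. MKI67, a marker of proliferating cells, was at 10.27 ± 0.12 in SA and 13.42 ± 0.23 in Ctrl (mean log2 value ± SD, n = 2 each). LDHA, which converts pyruvate to lactate, was at 17.35 ± 0.15 in SA and 19.23 ± 0.04 in Ctrl, and the stress-induced transcription factor ATF3 was at 8.70 ± 0.45 in SA and 5.36 ± 0.34 in Ctrl. Of 21070 genes tested with limma, 1312 were higher and 1801 lower in SA, and 611 and 736 with replicate number as a block. Protein-coding genes made up 914 of the higher and 1449 of the lower ones.

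The largest rises in SA were those of NCAM1, the adhesion molecule CD56, by 6.86 ± 0.31 (log2 difference ± SE), and of CFAP126, a cilium and flagellum protein, by 6.77 ± 0.15. NSG2 rose by 6.32 from a Ctrl level of 3.55, below the median of all probe sets, so the size of its rise depends on the background there. TMEM140 rose by 4.81, PIK3CG, a catalytic subunit of PI3-kinase, by 4.80, PLAAT4 by 4.67, the Notch target HEY1 by 4.20, RCAN2 by 3.97 and the protease CAPN2 by 3.91. EMP2, a tetraspan membrane protein, fell by 5.67 ± 0.17, and the integrin subunit ITGB7 fell by 5.15 ± 0.14. The chemokine CXCL10 fell by 4.64, NDNF by 4.33, CHRDL1 by 4.17, S100A4 by 4.12, the class II gene HLA-DOA by 3.97, APOBEC3D by 3.77, GNAL by 3.75 and TUBB2B by 3.72. Each of these had a limma adjusted p of at most 0.007 and remained called with the block. A second, dimmer probe set of NCAM1 differed by 0.01 and that of PIK3CG by 0.60.

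In the list of mitosis and G2/M genes, 34 of 37 fell in SA, 36 adjusted over the list alone, with a median of -1.40. The limma camera adjusted p was 1.79e-19, and adjusted p = 0.502 with an estimated correlation. MKI67 fell by 3.15 ± 0.20 and the spindle-associated HMMR by 2.47 ± 0.29. Of 36 DNA replication and G1/S genes, 30 fell, 34 adjusted over the list alone, with a median of -1.15 (adjusted p = 6.85e-18, and adjusted p = 0.387 with an estimated correlation). The transcription factor E2F8 fell by 2.53 ± 0.26 and the thymidine kinase TK1 by 2.35 ± 0.28. With the block, 22 genes of each of these lists were called. Of 33 replication-dependent histone genes, 10 fell, 15 adjusted over the list alone (median -0.58, adjusted p = 7.76e-06, and adjusted p = 0.562 with an estimated correlation), among them H2BC17 by 1.89 and H1-2 by 1.77; the block kept 8.

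Of 21 cholesterol synthesis genes, 10 fell in SA, 11 adjusted over the list alone (median -0.80, limma camera adjusted p = 9.04e-07, and adjusted p = 0.558 with an estimated correlation). MVD, a mevalonate pathway decarboxylase, fell by 2.93 ± 0.14, and HMGCS1, which makes HMG-CoA, by 1.81 ± 0.28. Of 18 genes of fatty acid synthesis and lipid droplets, 9 fell, 10 adjusted over the list alone (median -0.78, adjusted p = 0.000106, and adjusted p = 0.387 with an estimated correlation), and the fatty acid synthase FASN fell by 2.16 ± 0.29. Of 19 glycolysis genes, 10 fell, 17 adjusted over the list alone (median -0.76, adjusted p = 9.43e-07, and adjusted p = 0.558 with an estimated correlation). PFKFB3, which makes an activator of phosphofructokinase, fell by 2.54 ± 0.22, the isomerase TPI1 by 2.10 ± 0.20, LDHA by 1.89 ± 0.16 and the hexokinase HK2 by 1.55 ± 0.26. Of 20 hypoxia response genes, 7 fell and 1 rose, 12 and 2 adjusted over the list alone (median -0.52, adjusted p = 0.00975, and adjusted p = 0.562 with an estimated correlation). The vasoactive peptide gene ADM fell by 3.27 and the glucose transporter SLC2A1 by 2.07, and the secreted glycoprotein STC2 rose by 2.00. With the block, 7 genes each of the cholesterol, fatty acid and glycolysis lists and 7 falls and 1 rise of the hypoxia list were called.

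Further lists moved down by smaller medians in SA. Of 47 oxidative phosphorylation genes, 14 fell and 1 rose (18 and 2 adjusted over the list alone, median -0.46, limma camera adjusted p = 0.000636, and adjusted p = 0.588 with an estimated correlation). Of 31 proteasome genes, 8 fell (11 adjusted over the list alone, median -0.51, adjusted p = 0.000357, and adjusted p = 0.562 with an estimated correlation), and 0 were called with the block, which left 5 falls and 0 rises in oxidative phosphorylation. Of 26 genes of MYC and nucleolar ribosome biogenesis, 5 fell (7 adjusted over the list alone, median -0.45, adjusted p = 0.000636, and adjusted p = 0.558 with an estimated correlation). Of 29 ribosomal protein genes, 3 fell (0 adjusted over the list alone, median -0.38, adjusted p = 0.0014, and adjusted p = 0.637 with an estimated correlation). Of 17 TCA cycle genes, DLAT and IDH2 fell (2 adjusted over the list alone, median -0.32, adjusted p = 0.0274, and adjusted p = 0.562 with an estimated correlation). With the block, 4, 0 and 2 genes of these last 3 lists were called.

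Of 19 immediate early genes, 9 rose in SA, 11 adjusted over the list alone with 2 lower (median 0.68, limma camera adjusted p = 2.08e-05, and adjusted p = 0.481 with an estimated correlation). ATF3 rose by 3.34 ± 0.27 and JUN, a subunit of AP-1, by 3.06 ± 0.26. Of 31 genes of the integrated stress response, 10 rose and 1 fell, 11 and 2 adjusted over the list alone (median 0.38, adjusted p = 0.00071, and adjusted p = 0.502 with an estimated correlation). CHAC1, which degrades glutathione, rose by 2.30, and the asparagine synthetase ASNS by 1.86. Of 31 genes of the endoplasmic reticulum unfolded protein response, 8 rose and 2 fell, 8 and 3 adjusted over the list alone (median 0.24, adjusted p = 0.0072, and adjusted p = 0.558 with an estimated correlation), led by SEL1L, a component of the degradation machinery, at 2.31, and the chaperone DNAJB9, at 2.04. Of 21 plasma cell identity genes, 7 rose, 7 adjusted over the list alone with 1 lower (median 0.23, adjusted p = 0.0072, and adjusted p = 0.502 with an estimated correlation), among them TNFRSF17, the receptor BCMA, by 2.29, and CD79A by 2.22. The block kept 8 immediate early rises, 8 rises and 1 fall of the integrated stress response, 5 rises and 0 falls of the unfolded protein response, and 5 plasma cell rises.

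**Figure D1:**
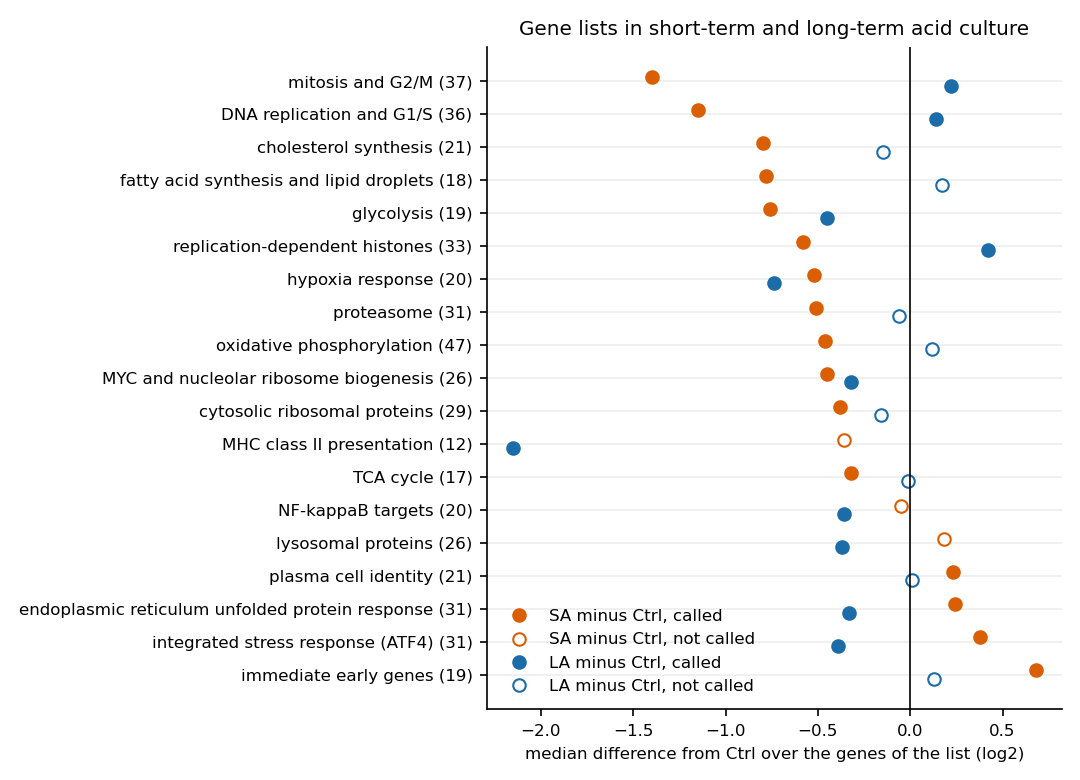
Median log2 difference from Ctrl over the kept genes of each list called in SA or LA (number of genes in brackets); filled points were called by camera at the preset correlation, open points were not. Mitosis and G2/M lies at -1.40 in SA and 0.22 in LA, and MHC class II presentation at -0.36 in SA and -2.15 in LA; with an estimated correlation 0 lists were called.

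The acid-handling lists were not called in SA. Of 16 acid and bicarbonate transport genes, 2 rose and 1 fell, 3 and 1 adjusted over the list alone; the median was -0.03, the mean 0.19 and the direction of the test up (limma camera adjusted p = 0.568). The voltage-gated proton channel HVCN1 rose by 2.35 ± 0.27. Of 17 V-ATPase genes, 2 rose, among them ATP6V0E1 by 1.53 ± 0.16 (adjusted p = 0.202). The cell death lists were not called either. Of 14 pro-death genes, 2 rose, BMF by 2.96 and PMAIP1 by 2.91, and 5 fell, BID by 1.79 (2 and 6 adjusted over the list alone, 2 and 1 with the block, limma camera adjusted p = 0.804). Of 9 pro-survival genes, 2 rose, among them BCL2 by 1.63, and 2 fell (5 and 3 adjusted over the list alone, 1 and 2 with the block, adjusted p = 0.393). PPARGC1A, a coactivator of mitochondrial genes, rose by 1.80, the autophagy receptor SQSTM1 by 2.54, and GLUL, which makes glutamine, fell by 3.25. Lists of markers of other cell types were not called: NCAM1 was the 1 called gene of 7 in the T and NK cell list, 0 of 8 and 0 of 7 genes were called in the monocyte and the stromal and endothelial lists, and ITGA2B and HBD, both lost with the block, in the erythroid and platelet list of 8.

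Protein-coding genes on some chromosomes were lower in SA as a group. On chromosome 9 the median SA minus Ctrl was -0.43 over 481 genes, with 143 lower and 6 higher, 73 and 2 with the block. On chromosome 22 it was -0.36 over 268 genes, with 75 lower and 3 higher, 32 and 0 with the block. Chromosomes 10 and 11 had medians of -0.30 and -0.28. Both SA arrays showed the shift. In stretches of about 40 neighbouring genes, all 12 medians on chromosome 9 lay between -0.69 and -0.24 and all 7 on chromosome 22 between -0.52 and -0.15. Stretches elsewhere were as low, and some formed runs of neighbours. On chromosome 3, stretches 1 to 7 of 16 lay between -0.50 and -0.20 and stretches 11 to 13 between 0.20 and 0.33. On chromosome 12, stretches 1 to 5 of 16 lay between -0.55 and -0.20 and stretches 11 to 13 between 0.20 and 0.28. On chromosome 16, stretch 12 of 13 lay at -0.62, between neighbours at -0.24 and -0.14. The named genes on chromosomes 9 and 22 are ABCA1, NDUFB6, PSMB7, RPL35, SEC61B, APOBEC3D, BID and CRELD2, and XBP1, at 0.23 and not called. All but XBP1 were lower and called in the fit without the block. MKI67, PFKFB3, LDHA, ADM and E2F8, all lower, lie on chromosomes 10 or 11. NCAM1 (6.86), PLAAT4 (4.67) and HBD (0.79), all higher, lie on chromosome 11. Outside these 4 chromosomes, 31 of 33 mitosis genes fell (median -1.37), 24 of 30 DNA replication genes (-1.06) and 6 of 14 glycolysis genes (-0.60). So did 4 of 15 hypoxia genes (-0.43), 9 of 38 oxidative phosphorylation genes (-0.31) and 10 of 33 histone genes (-0.58). The low stretches on chromosomes 3, 12 and 16 were not left out, so these counts are not free of such shifts.

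**Figure D2:**
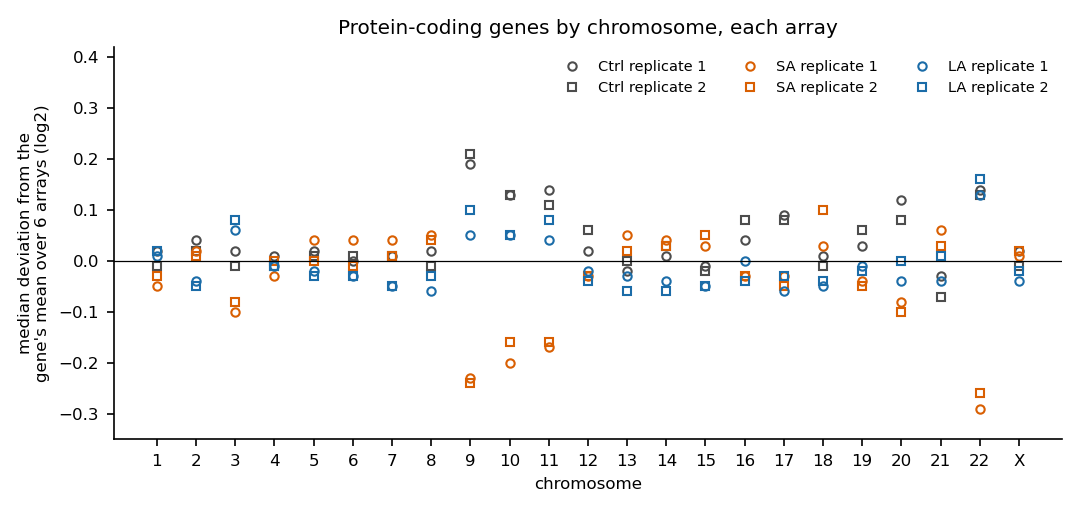
Median deviation of the protein-coding genes of each chromosome from their mean over the 6 arrays, in log2 units, for each array. On chromosome 9 the SA arrays lie at -0.23 and -0.24 and the Ctrl arrays at 0.19 and 0.21, and on chromosome 22 the SA arrays lie at -0.29 and -0.26.

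Time in culture differed between SA and Ctrl along with pHe. Leaving out any 1 array of the 2 groups gave 1134 to 2036 called genes in place of 3113.

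The comparison of LA with Ctrl asks what remains different in cells kept long-term at pHe 6.8, at the same time label as the control. The largest rise was that of CD180 and the largest fall that of SLAMF7. CD180, a Toll-like receptor relative of B cells, was at 17.04 ± 0.34 in LA and 7.51 ± 0.48 in Ctrl, and SLAMF7, a plasma cell surface receptor, was at 7.44 ± 0.04 in LA and 14.59 ± 0.16 in Ctrl (mean log2 value ± SD, n = 2 each). The lists of MHC class II presentation, hypoxia response and glycolysis moved down in LA cells in a set test at a preset correlation. With an estimated correlation, 0 of the 41 lists were called by limma camera and 1 had an unadjusted p under 0.05. With limma, 339 genes were higher and 336 lower in LA, and 162 and 117 with the block.

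CD180 rose by 9.53 ± 0.42, RANBP3L by 8.29 ± 0.28, the titin gene TTN by 6.98 and the methyltransferase TMT1A by 6.19. The chemokine receptor CCR1 rose by 5.76, SYCP3 by 4.72, ZNF852 by 4.26, GNPTAB, which tags lysosomal enzymes, by 3.79, the transcriptional inhibitor ID2 by 3.74 and the sphingosine phosphate receptor S1PR1 by 3.55. SLAMF7 fell by 7.15 ± 0.15, CD48, another SLAM family molecule, by 5.99 ± 0.41, HLA-DOA by 4.86 and the interleukin-6 receptor IL6R by 4.74. INHBE fell by 4.13, the heparan sulfatase SULF2 by 3.69, the osteopontin gene SPP1 by 3.32 (LA level 3.65, below the median of all probe sets), S100A11 by 3.31, ADM by 3.24 and WNT10A by 3.17. All 20 had a limma adjusted p of at most 0.022 and remained called with the block. A second probe set of IL6R differed by -0.21 and a dim second one of SULF2 by -0.08.

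**Figure D3:**
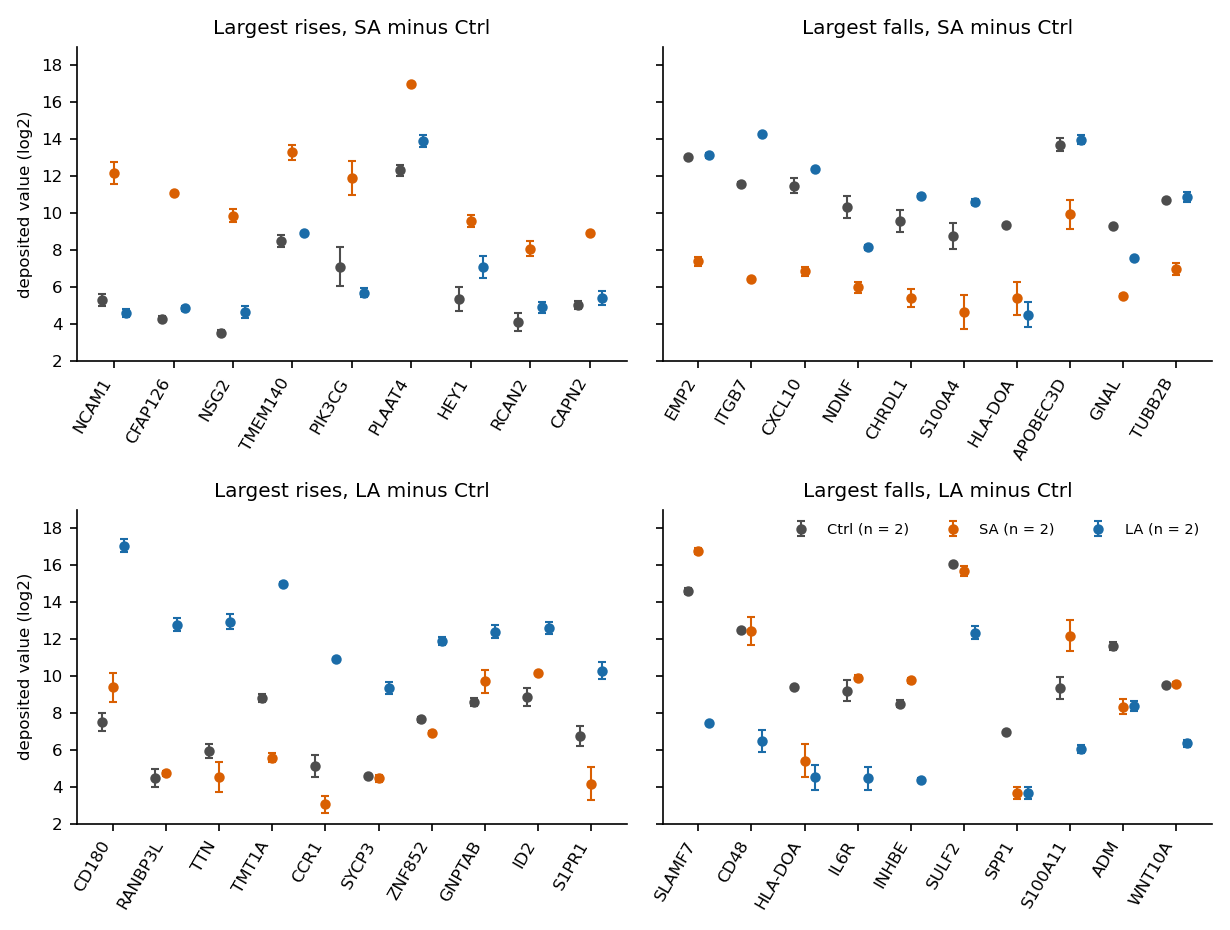
Group means (points) and SDs (bars) of the deposited log2 values, n = 2 arrays per group, for genes with the largest rises and falls against Ctrl in SA (top) and LA (bottom). NCAM1 lies at 12.18 in SA and 5.32 in Ctrl, and CD180 at 17.04 in LA and 7.51 in Ctrl.

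Of 12 MHC class II presentation genes, 9 fell in LA, 11 adjusted over the list alone and 8 with the block, with a median of -2.15 (limma camera adjusted p = 2.78e-11, and adjusted p = 0.415 with an estimated correlation). HLA-DOA fell by 4.86 ± 0.47, HLA-DQB1 by 2.55 ± 0.21 and the invariant chain CD74 by 1.51 ± 0.22. Of 20 hypoxia response genes, 6 fell, 15 adjusted over the list alone with 1 higher (median -0.74, adjusted p = 3.86e-08, and adjusted p = 0.415 with an estimated correlation), including ADM and the mitophagy gene BNIP3, which fell by 1.66. Of 19 glycolysis genes, 5 fell, 8 adjusted over the list alone (median -0.45, adjusted p = 5.02e-06, and adjusted p = 0.505 with an estimated correlation). HK2 fell by 2.59 ± 0.26 and HK1 by 1.45 ± 0.19, while LDHA differed by -0.20 (adjusted p = 0.54). With the block, 4 hypoxia genes and 2 glycolysis genes were called.

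Of 31 unfolded protein response genes, 4 fell in LA, 12 adjusted over the list alone with 1 higher (median -0.33, limma camera adjusted p = 9.72e-05, and adjusted p = 0.415 with an estimated correlation); HERPUD1 fell by 2.03, the 1 fall that the block kept. Of 31 integrated stress response genes, 6 fell and 1 rose, 12 and 1 adjusted over the list alone (median -0.39, adjusted p = 0.000586, and adjusted p = 0.415 with an estimated correlation), of which the block kept 1. Of 26 lysosomal genes, 3 fell, 7 adjusted over the list alone (median -0.37, adjusted p = 0.000386, and adjusted p = 0.415 with an estimated correlation), with SCARB2 lower by a log2 difference of -1.56, and the block kept 1. Of 20 NF-kappaB targets, ICAM1 and CD74 fell, both also with the block, 3 adjusted over the list alone with 2 higher (median -0.36, adjusted p = 0.0228, and adjusted p = 0.415 with an estimated correlation). Of 26 genes of MYC and ribosome biogenesis, 0 were called, 0 adjusted over the list alone, and the list was called (median -0.32, adjusted p = 0.000574, and adjusted p = 0.415 with an estimated correlation).

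Of 33 replication-dependent histone genes, 2 rose in LA, 4 adjusted over the list alone (median 0.42, limma camera adjusted p = 3.86e-08, and adjusted p = 0.551 with an estimated correlation), H4C4 by 1.98 and H2BC9 by 1.18, the latter lost with the block. Of 36 DNA replication genes, 3 rose, 6 adjusted over the list alone (median 0.14, adjusted p = 0.000912, and adjusted p = 0.415 with an estimated correlation). Of 37 mitosis genes, 1 rose, ANLN by 1.27, 2 adjusted over the list alone with 1 lower (median 0.22, adjusted p = 0.00402, and adjusted p = 0.614 with an estimated correlation). No member of the replication and mitosis lists was called with the block.

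Single genes of metabolism and identity also changed in LA. The mitochondrial dehydrogenase IDH2 rose by 3.48 ± 0.26, the fatty acid elongase ELOVL6 by 2.72 ± 0.15 and SLC25A20, the carnitine carrier of mitochondria, by 2.33 ± 0.19. CPT1A, which starts mitochondrial fatty acid oxidation, rose by 1.41, a call lost with the block. CD38 rose by 1.65 ± 0.14, ITGB7 by 2.72 ± 0.14 and the transcription factor MAF by 1.80 ± 0.17, and HVCN1 fell by 2.62 ± 0.27. The lists of acid and bicarbonate transport (16 genes, 1 lower, limma camera adjusted p = 0.794), V-ATPase (17 genes, 0 called, adjusted p = 0.543), oxidative phosphorylation (47 genes, 0 called, adjusted p = 0.186) and fatty acid oxidation (21 genes, 2 higher, adjusted p = 0.0663) were not called. On chromosome 12, the stretch of 40 neighbouring genes from SYCP3 to TMEM119, which holds GNPTAB, had a median LA minus Ctrl of 0.39 (SA 0.28), and the stretch from IQSEC3 to CHD4 one of -0.45 (SA -0.55). Of the other cell type marker lists, 1 gene of erythroid cells and platelets was called, HBD, and lost with the block.

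Leaving out any 1 array of the 2 groups gave 195 to 253 called genes in place of 675. The conflicting time labels of the LA cells leave open whether weeks or months at pHe 6.8 were measured.

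The comparison of LA with SA asks how long-term acid culture differs from short-term at the same pHe of 6.8, with time in culture as the difference the labels state. Lists of cell division, replication, sterol and fatty acid synthesis genes moved up in LA cells against SA cells, while lists of integrated stress response, unfolded protein response, lysosomal and MHC class II genes moved down, in a set test at a preset correlation. With an estimated correlation, 0 of the 41 lists were called by limma camera and 3 had an unadjusted p under 0.05. MKI67 was at 13.34 ± 0.27 in LA and 10.27 ± 0.12 in SA, and SEL1L at 14.37 ± 0.19 in LA and 17.50 ± 0.18 in SA (n = 2 each). With limma, 1834 genes were higher and 1526 lower in LA, and 1022 and 801 with the block. Leaving out any 1 array of the 2 groups gave 1503 to 2256 called genes. The chromosomes whose genes were lower in SA as a group were higher in this comparison. Median LA minus SA of protein-coding genes was 0.31 on chromosome 9, 0.39 on 22, 0.23 on 10 and 0.22 on 11. Their medians of LA minus Ctrl were -0.10, 0.04, -0.07 and -0.06. Removing each chromosome's median deviation gave 1575 genes higher and 1586 lower in LA than in SA.

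TMT1A was higher in LA by 9.41 ± 0.19, TTN by 8.40, RANBP3L by 8.03, ITGB7 by 7.87 ± 0.14, CCR1 by 7.85 from an SA level of 3.05, below the median of all probe sets, CD180 by 7.66, S1PR1 by 6.13, S100A4 by 5.97, EMP2 by 5.73 and CHRDL1 by 5.55. SLAMF7 was lower, at -9.32 ± 0.15, followed by NCAM1 at -7.57, PIK3CG at -6.22, CFAP126 at -6.22, S100A11 at -6.10, CD48 at -5.98, IL6R at -5.44, INHBE at -5.39, NSG2 at -5.21 and NIPAL2, a magnesium transporter family member, at -5.17. All 20 had a limma adjusted p of at most 0.0024 and remained called with the block.

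Of 37 mitosis genes, 34 were higher in LA than in SA, 36 adjusted over the list alone (median 1.70, limma camera adjusted p = 1.05e-22, and adjusted p = 0.4 with an estimated correlation), and of 36 replication genes 33, 34 adjusted over the list alone (median 1.43, adjusted p = 5.5e-22, and adjusted p = 0.229 with an estimated correlation). Of 33 histone genes, 21 were higher, 28 adjusted over the list alone (median 1.19, adjusted p = 2.37e-13, and adjusted p = 0.549 with an estimated correlation). Of 18 fatty acid synthesis genes, 10 were higher, 11 adjusted over the list alone with 1 lower (median 0.87, adjusted p = 4.03e-06, and adjusted p = 0.229 with an estimated correlation), led by ELOVL6 at 4.15. Of 21 cholesterol synthesis genes, 11 were higher and 1 lower, the same numbers adjusted over the list alone (median 0.89, adjusted p = 7.92e-05, and adjusted p = 0.599 with an estimated correlation). Oxidative phosphorylation (10 of 47 higher, 17 adjusted over the list alone, median 0.40, adjusted p = 4.03e-06, and adjusted p = 0.775 with an estimated correlation) included NDUFV2 at 2.64. Proteasome genes (4 of 31 higher, 3 adjusted over the list alone, median 0.29, adjusted p = 0.00418, and adjusted p = 0.775 with an estimated correlation) and TCA cycle genes (3 of 17 higher, 3 adjusted over the list alone, median 0.33, adjusted p = 0.0415, and adjusted p = 0.775 with an estimated correlation) were also higher, IDH2 at 4.73. With the block, 32 mitosis, 30 replication, 20 histone, 9 fatty acid, 9 cholesterol, 5 oxidative phosphorylation, 2 proteasome and 3 TCA cycle genes were higher, and 0 cholesterol genes lower.

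Of 31 integrated stress response genes, 13 were lower in LA than in SA and 1 higher, 16 and 1 adjusted over the list alone (median -0.55, limma camera adjusted p = 5.43e-08, and adjusted p = 0.229 with an estimated correlation); CHAC1 was at -3.50 and STC2 at -3.48. Of 31 unfolded protein response genes, 10 were lower and 1 higher, 17 and 4 adjusted over the list alone (median -0.46, adjusted p = 1.89e-05, and adjusted p = 0.4 with an estimated correlation), with SEL1L at -3.14 and the stress sensor ERN1 at -3.00. Of 26 lysosomal genes, 13 were lower and 2 higher, 18 and 2 adjusted over the list alone (median -0.60, adjusted p = 4.1e-06, and adjusted p = 0.4 with an estimated correlation). Of 12 MHC class II genes, 8 were lower, 10 adjusted over the list alone (median -1.64, adjusted p = 2.25e-07, and adjusted p = 0.5 with an estimated correlation), HLA-DRB1 at -2.32 and HLA-DQA1 at -2.29. Of 19 immediate early genes, 8 were lower and 3 higher, 10 and 3 adjusted over the list alone (median -0.62, adjusted p = 0.00125, and adjusted p = 0.4 with an estimated correlation), ATF3 at -3.46. Of 21 plasma cell identity genes, 7 were lower and 3 higher, 10 and 4 adjusted over the list alone (median -0.22, adjusted p = 0.00987, and adjusted p = 0.4 with an estimated correlation), with TNFRSF17 at -2.70 and CD38 at 1.64. With the block, 11 integrated stress response, 8 unfolded protein response, 7 lysosomal, 7 MHC class II, 8 immediate early and 6 plasma cell genes were lower, and 1, 0, 2, 0, 1 and 2 were higher.

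Among the genes followed in every comparison whether called or not, the plasma cell factors IRF4 (0.28 in SA and -0.16 in LA against Ctrl), XBP1 (0.23 and 0.01) and SDC1 (-0.54 and -0.74) were not called against Ctrl, nor were the chemokine receptor CXCR4 (0.48 and 0.47), MYC (0.51 and -0.34), MCL1 (0.68 and 0.07), BCL2L1 (-0.54 and 0.16), the carbonic anhydrase CA12 (-0.13 and -0.16), the proton sensor GPR65 (0.32 and -0.18) and NSD2, the target of the t(4;14) translocation (-0.71 and 1.02). PRDM1 was called at 0.60 in SA, a call lost with the block, and was at 0.23 in LA. In LA, SLC2A1 was at -1.42, BCL2 at 0.75, TNFRSF17 at -0.40 and PPARGC1A at -0.27, none called, and in SA, CPT1A was at -0.81 and CD38 at 0.01, not called. In LA minus SA, 10 of these 19 genes were called with limma: LDHA (1.69), NSD2 (1.72), CD38, CPT1A (2.22), PPARGC1A (-2.07), TNFRSF17, and, lost with the block, MYC (-0.85), HK2 (-1.04), BCL2 (-0.88) and BCL2L1 (0.70). The other 9 lay between -0.62 and 0.65.

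The last comparison asks which differences of SA cells were also present in LA cells. Against Ctrl, 101 genes were higher and 120 lower in both acid groups, among them HLA-DOA, SPP1, ADM and HK2 on the lower side and CD180 on the higher side. Calls independent of each other would give 21.1 and 28.7. With the block, 34 genes were higher and 34 lower in both. Another 53 genes were higher in SA and lower in LA, and 56 lower in SA and higher in LA. Independent calls would give 20.9 and 29, and the block gave 16 and 22. Calls of either kind exceeded the numbers for independent calls. Both comparisons share their Ctrl arrays, so those are not the numbers to expect without shared change. Genes higher in SA than in both Ctrl and LA numbered 827, and genes lower in SA than in both numbered 1022, 390 and 460 with the block. The chromosomes that were lower in SA as a group were not set apart in these numbers. Genes that differed in LA from both Ctrl and SA in the same direction numbered 226 higher and 182 lower, 121 and 73 with the block. Across genes, which are not independent replicates, SA minus Ctrl and LA minus Ctrl had a Pearson correlation of 0.23 and a Spearman correlation of 0.30, where groups without any change that share control arrays gave 0.50 and 0.46 in simulations. The share of genes with the same sign was 62%, below the simulated mean of 66.7%. Change in only 1 acid group lowers the correlations and this share, so values below the simulated ones do not show less shared change. The covariance was 0.0656, above the simulated mean of 0.0489 and maximum of 0.0515. The simulated genes were drawn independently of each other, so that maximum leaves out errors shared by genes. The excess therefore does not decide whether change was shared.

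**Figure D4:**
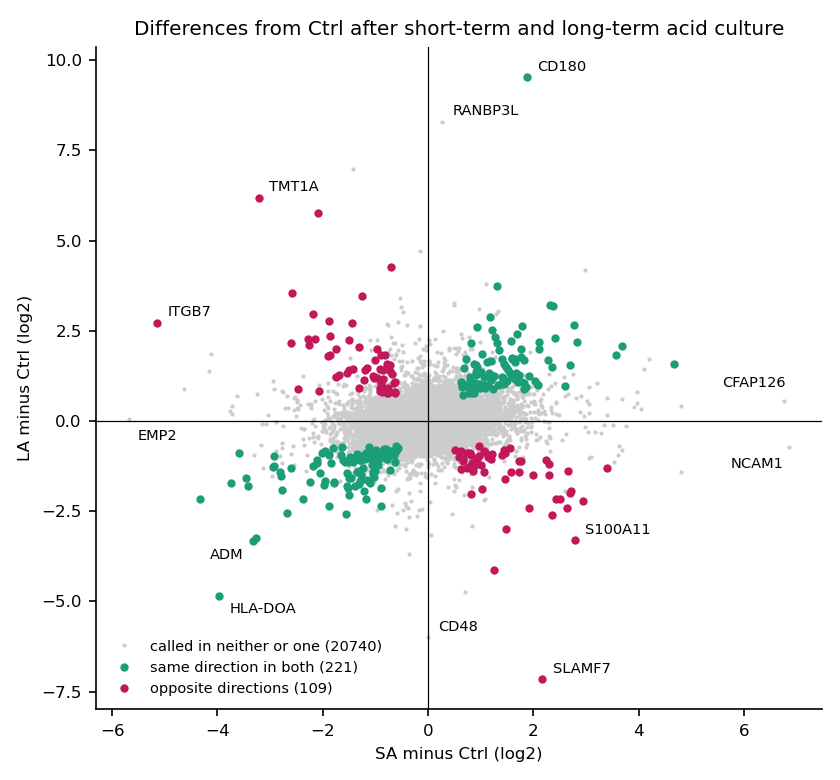
Log2 difference from Ctrl in SA (horizontal axis) and LA (vertical axis), each point a gene; colour marks the 221 genes called the same way in both and the 109 called in opposite directions. CD180 lies at 9.53 in LA and 1.87 in SA, and SLAMF7 at -7.15 in LA and 2.17 in SA.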

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

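The differences between LA and SA given here belong to a comparison planned beforehand, while the test of probe sets without a gene symbol was chosen only after the result was seen. Against Ctrl, 109 genes were called in opposite directions in SA and LA with limma, 38 with replicate number as a block, and all 109 were also called in LA minus SA, which follows almost of itself from opposite calls against the same Ctrl arrays. ITGB7, an integrin subunit of plasma cell homing, was at -5.15 in SA and 2.72 in LA, a difference between LA and SA of 7.87. SLAMF7 was at 2.17 in SA and -7.15 in LA, a difference of -9.32. TMT1A (9.41), the chemokine receptor CCR1 (7.85, from an SA level of 3.05, below the median of all probe sets) and the sphingosine phosphate receptor S1PR1 (6.13) were higher in LA than in SA, as was ZNF852 (4.96), whose own call in SA, at -0.71, was lost with the block (limma adjusted p = 0.13). Further ZNF852 probe sets of about the same brightness differed by 0.14 and -0.05 in SA minus Ctrl, so its fall in SA is not borne out, while they differed by 4.16 and 4.41 in LA minus Ctrl. INHBE (-5.39), S100A11 (-6.10) and NIPAL2 (-5.17) were lower in LA than in SA, after a rise in SA and a fall in LA.

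Probe sets that carry no gene symbol took no part in the comparisons of genes. Tested on their own with limma, 38 were called in SA minus Ctrl, 13 higher and 25 lower, 18 in LA minus Ctrl, all higher, and 145 in LA minus SA, 108 higher and 37 lower. What they measure is not given in the sources used here.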

How the results depend on the processing

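Removing each chromosome's median deviation was the 1 alternative chosen only after the result was seen. Replicate number as a block lowered the counts of called genes most among the models, to 1347 in SA minus Ctrl, 279 in LA minus Ctrl and 1823 in LA minus SA, from 3113, 675 and 3360, and the genes called the same way in SA and LA to 68 from 221. The difference by replicate number is almost absent from the values, so the fit without the block counts 1 degree of freedom too many. All calls made with the block were also made without it, in the same direction.

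Testing every probe set in place of 1 per gene gave 982, 190 and 1840 called probe sets, 31 called the same way in SA and LA, and r = 0.34 in place of 0.23; the cause was not tested. An added 2-fold limit gave 1541 genes in SA minus Ctrl, 1847 in LA minus SA and 124 called the same way in both acid groups, which a stricter threshold must lower. An unadjusted p under 0.05 with a 2-fold limit gave 1743 in SA minus Ctrl and 1988 in LA minus SA. A threshold of 0.10 on the adjusted p gave 4919 in SA minus Ctrl and 1507 in LA minus Ctrl, with 608 called the same way.

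Leaving out 1 array at a time gave 1134 (without Ctrl 2) to 2486 genes (without either LA array) in SA minus Ctrl, 195 (without LA 1) to 674 (without either SA array) in LA minus Ctrl, and 1503 (without LA 1) to 2931 (without either Ctrl array) in LA minus SA. Genes called the same way numbered 57 (without Ctrl 2) to 175, and r ran from 0.21 to 0.31. Fewer arrays give fewer degrees of freedom. Of the 20 largest named changes, 20 in SA minus Ctrl, 18 in LA minus Ctrl and 20 in LA minus SA were kept in every setting. The exceptions were S100A11 and S1PR1, only with an LA array left out.

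With an estimated correlation between genes, 0 lists were called in SA minus Ctrl, 0 in LA minus Ctrl and 0 in LA minus SA, against 16, 11 and 14 at the preset correlation. With fry, 19 lists were called in LA minus Ctrl. Over all comparisons, fry lost 9 calls made at the preset correlation and added 23 in the same direction. In SA minus Ctrl, the lists lost were oxidative phosphorylation, TCA cycle, proteasome, ribosomal proteins and histones (fry adjusted p from 0.0691 to 0.133). In LA minus Ctrl they were mitosis (fry adjusted p = 0.32) and histones (0.0977). In LA minus SA they were oxidative phosphorylation (0.0714) and proteasome (0.0923). The homing, adhesion and bone disease list, not called in SA minus Ctrl at the preset correlation, was called in the other direction with fry (limma adjusted p = 0.0262, median 0.11). Among named genes, 5235 of 5803 values were the same in the alternatives, 538 weaker, 30 stronger and 0 reversed. With the block, 78 of the 342 named results lost their call.

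Scaling moved the balance of directions. The share of called genes that were higher in SA was 42.1% as deposited, 51.1% after cyclic loess and 52.1% after removing chromosome medians. In LA minus Ctrl the balance turned with the scaling: 339 higher and 336 lower as deposited (50.2% higher), 304 and 378 (44.6%) after another quantile normalization, and 409 and 305 (57.3%) after cyclic loess. The share higher in LA than in SA was 54.6%, and 46.1% after another quantile normalization.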

Other observations

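The tests of bright-gene shares, gene density, brightness and scaling, other small RNAs and the replicate term, and the resampling interval, were chosen only after the result was seen; those of copy number, genes not called, host genes and quantile normalization were written before. Small nucleolar RNAs, which guide the modification of ribosomal and spliceosomal RNA, were mostly higher in SA cells than in Ctrl. Of their differences, 78.6% lay above 0. They were not among the fixed lists, and no set test was run on them. Of 196 such genes, 66 were higher and 1 lower with limma, 53 and 0 with replicate number as a block, with a median of 0.55. The 20 small Cajal body RNAs had a median of 1.68, with 12 higher. SCARNA21 rose by 4.04 ± 0.29 and SNORD71 by 3.41 ± 0.27, both picked after their values were seen. In LA minus Ctrl the median of the class was 0.14, with 2 higher and 1 lower.

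Possible sources of this rise were tested on other RNAs. More small RNA of all kinds in the SA labelling would raise other small RNAs as well. The 119 bright ones had a median of 0.17, where 107 bright small nucleolar RNAs had 1.03. Of the 119, 81 were miRNA genes (median 0.19) and 30 snRNA genes (0.13), and 1 RNase P RNA gene was at 0.99. Carry-over of only some sizes or kinds of small RNA was not tested. Higher transcript levels of the host genes would put the hosts above 0, but the 59 hosts had a median of -0.30. Of the 196 small nucleolar RNA genes, 88 had a host kept, and 87.5% of these 88 lay above their host. The 88 share the 59 hosts and are not independent pairs. Many copies of SNORD113 and SNORD114 were set against the same host, MEG8, at -0.12. RNAs without a kept host were not covered by this test. Hosts were assigned by position without strand, and that explanation was reworded from transcription to transcript levels after the result. Slower decay or altered processing of these RNAs could produce the pattern and was not measured.

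Protein-coding genes on chromosomes 9 and 22 were lower in SA, in 12 of 12 and 6 of 7 stretches of neighbouring genes by more than 0.2, and a different number of copies there cannot be told apart from other causes. Probe sets without a gene symbol differed by -0.04 (95% interval by resampling -0.08 to 0.00), which met the limit set beforehand against copy number, but they hardly varied beyond replicate noise (spread 0.331 against 0.275; coding genes 0.619 against 0.207), so they are not shown to follow gene dosage, a reason found after the result. Regulated genes that happen to lie there would leave most others unmoved. Of bright genes there, 89.6% lay below the median elsewhere. The 2 chromosomes have the lowest medians in these same values, so this share largely restates the pattern and decides nothing. Genes not called differed by -0.14, between the bounds set. That decides nothing either, since regulated genes can stay uncalled with 2 arrays per group. Gene density would also lower chromosomes 17 and 19, which had a median of -0.09, and brightness or scaling would not leave -0.32 after cyclic loess. Copy number was not measured, and time in culture or a separate lineage of the SA cells may also contribute and was not tested.

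Replicate number held 1.18% of the within-group sum of squares. A replicate term removed before deposit would likely leave such a share, while quantile normalization alone left at least 32.6% in 20 simulated sets. Genes in those sets were drawn independently of each other, so errors shared by genes were not covered. With so little difference by replicate number left, the p-values of the fit without the block are too small.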
